A study of Homo sapiens with 12 samples.

How the data were processed

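Total RNA from U87 glioma cells was hybridized to 12 Illumina bead arrays, 3 for each combination of siRNA (control or BCL3) and treatment (DMSO or TMZ), per the labels. Per the labels, RNA was extracted with Trizol and a column with DNase, checked on a Bioanalyser, and amplified to biotin-labelled cRNA with an Ambion kit. The deposited bead-averaged probe intensities of 47320 probes, from 72.8 to 20797.5 on a linear scale, had not been normalized by the authors or background-subtracted. The file headers name the detection p-values but not their samples. Each such column was matched to the intensity column with which its values fell most strongly. A detection p-value falls as its intensity rises, as the share of background controls at least as bright. A separate deposited table held intensity values that the authors had background-subtracted and quantile-normalized, judged from the values, which ran from -14.1 to 18425.3 on a linear scale; each column ranked probes as the raw column of its sample did, with a Spearman correlation of at least 0.9999. The software and settings used for scanning and normalization are not given in the sources used here. The number of arrays limits the precision of every value.

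Raw intensities were corrected with neqc of limma 3.58.1 in R 4.3.3, with negative controls inferred from the detection p-values, an offset of 16, quantile normalization and log2. Probes with a detection p-value under 0.01 on at least 3 of 12 arrays were kept, 18105 in all. Of all probes 30112 carried exactly 1 gene symbol, 8 carried several and 17200 none; 30073 were found by Entrez identifier in the RefSeq gene table, with 0 symbols changed. Of the kept probes 14270 were named and 3835 were not. The brightest probe represented each gene, which left 10686 genes. The gene table served for names only, and no coordinates were used. MGMT, with 1 probe, and MPG, with 3 probes, did not pass the detection filter and were not tested.

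A group-means model was fitted to all 12 arrays with lmFit and eBayes of limma, with 8 residual degrees of freedom, and 5 comparisons were taken from it: BCL3 siRNA against control siRNA under DMSO and under TMZ, TMZ against DMSO with each siRNA, and the interaction. P-values were 2-sided and adjusted by Benjamini and Hochberg over the genes tested, with a threshold of 0.05; a gene past it is described as risen or fallen. Fold changes are on the offset scale and are given as log2 unless called fold. Errors of fold changes are limma standard errors on the log2 scale. The 25 gene lists were written from general knowledge, and the 23 with at least 5 measured members were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance 1 way, were alternatives. The estimated version gave higher p-values also for some lists with an estimate below the preset. For p53 targets with TMZ and control siRNA (0.002) the unadjusted camera p went from 3.43e-26 to 2.37e-06. Failing to pass with an estimated correlation thus does not by itself show that a list holds correlated genes. Among lists that passed with the preset in some comparison, the highest estimates were 0.076 for interferon response and for hypoxia response. Extracellular matrix and adhesion came next with 0.051. For these lists correlation between members may account for a lost call. Members were also adjusted over the list alone. Similarity of effects was measured across genes by Pearson and Spearman correlation.

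Groups, tests, lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule named BCL3; a fixed set with CA2, CDKN1A, MDM2, MGMT, CCND1, STAT3, NFKB1, NFKB2, RELA, RELB, MSH6 and MPG in every comparison; per comparison the 12 largest rises and 12 largest falls among called genes without overlap between groups; the 5 genes with the lowest p where fewer than 5 were called; and per list up to 4 called members with the lowest p, or up to 2 members where none was called. Uncharacterised model names were left out. A gene that an alternative or another probe puts in doubt is described with that value. Alternatives were normexp by maximum likelihood with an offset of 50, no background correction, median scaling, cyclic loess, an offset of 50, the authors' normalized intensities, no filter, detection on all 12 arrays, detection p-value under 0.05, averaged probes, only the 6 arrays compared, the replicate number as a block, trend and robust moderation, array weights, at least 1.5-fold change, and each array left out in turn. Effects of TMZ and of BCL3 siRNA averaged over the other factor were added after the data were seen, as was a fit with the log2 mean raw intensity of each array as a covariate, used for the hypoxia list. Tested on simulated data for TMZ with control siRNA, the steps recovered 65 of 100 genes changed by 0.5 log2 units. The median fitted change of these 100 was 0.40. Of 100 genes changed by 1 log2 unit 96 were recovered, and there were 3 false calls. The simulated noise was independent between probes, and genes changed only in the group with control siRNA and TMZ. The simulation held no effect of BCL3 siRNA, so error rates in the real data may differ.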

Results

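Transcript levels were measured in U87 cells, an established human glioma line, with Illumina bead arrays carrying 47320 probes. The cells had been transfected with siRNA against BCL3, an atypical member of the I-kappa-B family that acts in the nucleus with NF-kB proteins, or with a control siRNA. They were then treated with temozolomide (TMZ), an alkylating drug used against glioblastoma, at 100 µM for 24 h, or with its solvent DMSO. The 4 combinations had 3 arrays each, 12 in all. Mean raw intensity was 292.2 ± 25.8 (SD, n = 3) with control siRNA and DMSO, 262 ± 1.4 with control siRNA and TMZ, 247.8 ± 15.8 with BCL3 siRNA and DMSO and 267 ± 22.1 with BCL3 siRNA and TMZ. Between 16381 and 17839 probes were detected per array, 34.62% to 37.7% of the probes. Correlations of log2 values between arrays of one group ran from 0.9956 to 0.9972, and the lowest between any 2 arrays was 0.9822. The first principal component carried 61.9% of the variance and placed all arrays of BCL3 siRNA between 13.67 and 16.15 and all arrays of control siRNA between -16.88 and -14.08. The second, with 9.4%, placed the TMZ arrays between -8.56 and -1.08 and the DMSO arrays between 2.88 and 8.68. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision.

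BCL3, the targeted transcript, was lower on every array of BCL3 siRNA than on any array of control siRNA. Its normalized log2 intensity was 7.37 ± 0.11 (SD, n = 3) with control siRNA and DMSO and 6.38 ± 0.09 with BCL3 siRNA and DMSO, a log2 fold change of -0.98 (SE 0.07, adjusted p = 3.04e-07). Under TMZ it was 7.30 ± 0.06 with control siRNA and 6.54 ± 0.02 with BCL3 siRNA, a log2 fold change of -0.76 (SE 0.07, adjusted p = 3.1e-06). TMZ itself gave a BCL3 log2 fold change of -0.07 with control siRNA (adjusted p = 0.696) and 0.16 with BCL3 siRNA (adjusted p = 0.297), neither past the threshold. The knockdown left about 1.98-fold less signal under DMSO and 1.69-fold less under TMZ, on a scale that includes an offset of 16 and so understates changes of dim probes.

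**Figure D1:**
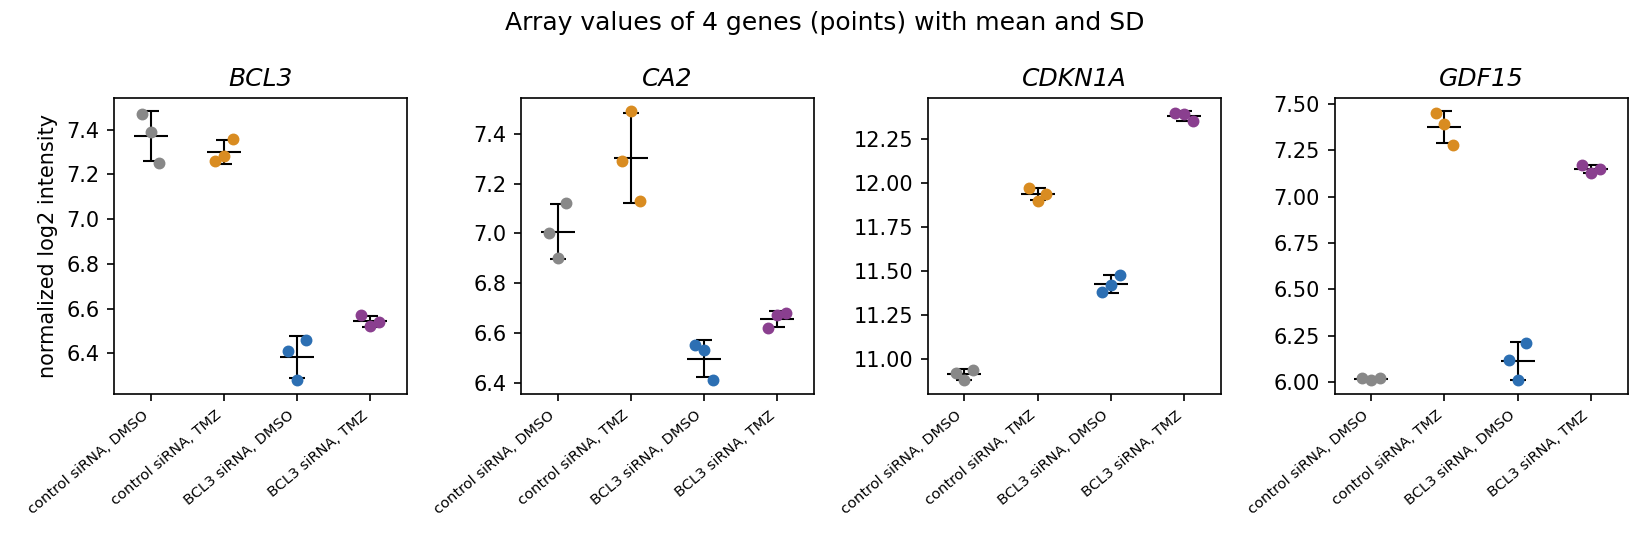
Normalized log2 intensity (y axis) of BCL3, CA2, CDKN1A and GDF15 on each of the 12 arrays, by group (x axis); points are arrays, the horizontal line is the mean of 3 arrays and the whiskers are 1 SD. Each panel has its own y scale that does not start at 0. BCL3 lay between 6.28 and 6.57 on arrays of BCL3 siRNA and between 7.25 and 7.47 on arrays of control siRNA, and CDKN1A was higher with TMZ and higher with BCL3 siRNA.

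The first comparison asked what BCL3 siRNA changed in cells given DMSO only. HMOX1, the haem-degrading enzyme induced by oxidative stress, rose 4.48-fold (log2 fold change 2.16, SE 0.06, n = 3 per group, adjusted p = 2.3e-10). F3, the tissue factor that starts blood coagulation, rose 4.33-fold (SE 0.07 on the log2 scale), and CDK6, a cyclin-dependent kinase of the G1 phase, rose 3.75-fold (SE 0.06). Among the largest falls, FKBP1A, the binding protein of the drug FK506, fell by 1.84 on the log2 scale (SE 0.11), G3BP2, a stress granule protein, fell by 1.83 (SE 0.05) and GLO1, the glyoxalase that removes methylglyoxal, fell by 1.75 (SE 0.07). Of the 10686 genes tested, 2213 rose and 2149 fell, together 40.8%. Most changes were small, with a median absolute log2 fold change of 0.35 among called genes; 246 rose and 408 fell by at least 1.5-fold, and 23 rose and 82 fell by at least 2-fold.

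The other largest rises under DMSO were those of EIF4EBP2 (1.43), STX3 (1.38), the deubiquitinase YOD1 (1.27), the histone gene H2BC5 (1.27), the stress-induced SESN1 (1.24), the muscle atrophy ubiquitin ligase subunit FBXO32 (1.23), the phosphatase DUSP5 (1.22), C3orf52 (1.21) and ADAM19 (1.13), given as log2 fold changes with standard errors of 0.05 to 0.09. The other largest falls were those of CSF3, the granulocyte colony-stimulating factor (-1.72, SE 0.13), ABCF2 (-1.55), TCEAL9 (-1.55), the channel AQP9 (-1.53), LRRC58 (-1.50), PPP2CA, a catalytic subunit of protein phosphatase 2A (-1.48), TRIM5 (-1.47), HEBP1 (-1.44) and VOPP1 (-1.43). Among the called genes 4195 had no overlap between the 3 arrays of one group and the 3 of the other, as had 50% of all genes tested, where chance gives 10%. For FKBP1A, 1 of its 3 other probes was called in the opposite direction (0.18).

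Among genes fixed in advance, carbonic anhydrase CA2 fell by 0.51 (SE 0.09, adjusted p = 0.000519), from 7.00 ± 0.11 to 6.50 ± 0.08 (SD, n = 3). CDKN1A, which encodes the cell cycle inhibitor p21, rose by 0.51 on the log2 scale (SE 0.05, adjusted p = 9.44e-06). NFKB1 rose (0.32, adjusted p = 0.00187) and RELA fell (-0.33, adjusted p = 0.00174). STAT3 (-0.26, adjusted p = 0.0205) and cyclin D1, CCND1 (-0.19, adjusted p = 0.0168), fell. The STAT3 call did not hold without any 1 of control siRNA with DMSO replicate 1 (adjusted p = 0.0831), BCL3 siRNA with DMSO replicate 1 (0.0582) or replicate 2 (0.0727). That of CCND1 did not hold without control siRNA with DMSO replicate 3 (0.0605) or BCL3 siRNA with DMSO replicate 1 (0.0654), with median scaling (0.587) or with only the 6 arrays compared in the fit (0.0503). NFKB2 (-0.15, adjusted p = 0.169), RELB (-0.20, 0.0606), MDM2 (-0.25, 0.107) and the mismatch repair gene MSH6 (0.15, 0.122) did not pass. RELB passed without control siRNA with DMSO replicate 2 (0.0288) and MDM2 without its replicate 1 (0.0192); RELB also passed with detection on all 12 arrays (0.0465), NFKB2 with averaged probes (0.0271), and MSH6 with median scaling (0.0307), no background correction (0.0492) and trend and robust moderation (0.0492).

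Genes of DNA replication fell together. Of 32 measured genes of the G1/S and DNA replication list, 19 fell and 0 rose (0 rose and 21 fell when adjusted over the list alone), with a median log2 fold change of -0.258; MCM6 of the replicative helicase (-0.54), POLE2 of DNA polymerase epsilon (-0.73) and E2F2 (-0.73) were among them. The list was lower than other genes by camera of limma (adjusted p = 2.53e-06), and this held with an estimated correlation (adjusted p = 0.00681). Of 35 genes of G2/M and mitosis, 13 fell and 2 rose (13 and 2 adjusted over the list alone), among them the mitotic kinesin KIF20A (-1.13), the survivin gene BIRC5 (-1.01), the proliferation marker MKI67 (-1.08) and the kinesin KIF11 (-0.74). This list passed with camera's preset correlation (adjusted p = 0.017) but not with an estimated one (adjusted p = 0.152 with an estimated correlation). Of 23 homologous recombination and Fanconi anaemia genes, 14 fell and 0 rose (14 and 1 adjusted over the list alone), including RAD51C (-0.39), FANCL (-0.53) and FANCG (-0.40). The adjusted p by camera was 0.017, and adjusted p = 0.128 with an estimated correlation. That estimate, -0.001, was below the preset 0.01, so correlation within the list does not account for the loss.

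Of 27 measured NF-kB targets 11 fell and 5 rose (12 and 5 adjusted over the list alone). The urokinase gene PLAU fell by 1.23 (SE 0.07), and IL1B fell by 1.37 (SE 0.08), while IL1A rose by 0.99 (SE 0.06). The list includes BCL3 itself. Its camera test gave adjusted p = 0.0322, and adjusted p = 0.153 with an estimated correlation; without BCL3 siRNA with DMSO replicate 1 the preset test gave 0.0541. Of 32 interferon response genes 10 fell and 1 rose (10 and 0 adjusted over the list alone), led by IFI44L (-1.18, while its other probe gave 0.03), SAMD9L (-0.52), ISG15 (-0.45) and IRF9 (-0.43). The adjusted p was 0.0322, adjusted p = 0.356 with an estimated correlation, and 0.128 without BCL3 siRNA with DMSO replicate 1; it also missed the threshold when probes had to be detected on all 12 arrays (0.0525) and when probes were averaged (0.055).

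The hypoxia response list was higher with the preset correlation (adjusted p = 0.00806) but not with an estimated one (adjusted p = 0.185 with an estimated correlation). Of 26 measured members 11 rose and 1 fell (11 and 1 adjusted over the list alone): the glucose transporter SLC2A1 rose by 1.07 on the log2 scale (SE 0.06), NDRG1 by 0.87 (SE 0.08), the collagen hydroxylase P4HA1 by 0.61 (SE 0.06) and adrenomedullin, ADM, by 0.54 (SE 0.07). Of 31 ribosomal protein genes 7 rose and 0 fell (6 and 0 adjusted over the list alone), by small amounts such as 0.33 for RPL5 and 0.34 for RPL34, with adjusted p = 0.023, and adjusted p = 0.152 with an estimated correlation. Of 36 p53 target genes 14 rose and 3 fell (14 and 3 adjusted over the list alone), with SESN1, PPM1D (0.73), TNFRSF10B (0.59) and CDKN1A up and CYFIP2 (-0.65) down, and the list as a whole did not pass (adjusted p = 0.0522). With cyclic loess, an offset of 50 or array weights, 3 higher lists passed under DMSO in place of 2. The p53 targets were nearest to the threshold among the other higher lists.

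Other lists held changes in both directions and did not pass as lists. Of 34 mesenchymal glioblastoma markers 10 rose and 7 fell (adjusted p = 0.856): ACTA2 (0.78) and COL5A1 (0.80) rose, and CD44 (-0.65) and podoplanin, PDPN (-0.84), fell. Of 32 extracellular matrix and adhesion genes 11 rose and 9 fell (adjusted p = 0.51), with the integrin ITGA5 (0.86), CCN1 (0.86) and SPARC (0.71) up. Of 37 unfolded protein response and ATF4 target genes 10 rose and 6 fell (adjusted p = 0.613); the amino acid transporter SLC7A5 rose by 0.90 on the log2 scale, and the serine synthesis enzyme PSAT1 (-0.94) and DDIT3 (-0.59) fell. Among 19 genes of cholesterol biosynthesis 6 rose and 5 fell (adjusted p = 0.965), among 26 apoptosis regulators 7 and 5 (0.865), among 24 STAT3 targets 3 and 7 (0.266), and among 26 heat shock and oxidative stress genes 4 and 6 (0.856), a list whose mean was above 0 while its median and test pointed down. Of 15 mismatch repair and alkylation repair genes 1 rose and 3 fell (0.735), with OGG1 (-0.52) and XRCC1 (-0.37) down. Counts of risen and fallen genes were 1 and 2 of 13 in the NF-kB and I-kappa-B family (0.814), 1 and 3 of 9 proneural markers (0.856), 2 and 1 of 6 drug efflux transporters (0.346), 2 and 4 of 10 stemness markers (0.51) and 2 and 5 of 33 oxidative phosphorylation genes (0.814). The NF-kB and I-kappa-B family and the STAT3 targets include BCL3 itself, which is counted among the fallen genes of both. Of 4 carbonic anhydrases measured 2 fell and 0 rose, too few for a test of the list. Markers of other cell types did not pass: leukocyte markers, 1 risen and 3 fallen of 7 (0.346), and neuron and oligodendrocyte markers, 1 and 3 of 6 (0.203); of 3 epithelial markers 1 fell and 0 rose, with no test.

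The split of calls into rises and falls depended on the scaling between arrays. Median scaling in place of quantile normalization called 3140 rises and 1673 falls under DMSO, 65.2% rises against 50.7%.

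The second comparison repeated the contrast of the siRNAs in cells given TMZ. HMOX1 rose 4.43-fold (log2 fold change 2.15, SE 0.06, n = 3 per group, adjusted p = 2.12e-10), F3 4.29-fold and CDK6 3.63-fold, and FKBP1A (-1.95, SE 0.11), G3BP2 (-1.93, SE 0.05) and GLO1 (-1.67, SE 0.07) fell. In all 1986 genes rose and 2155 fell, 38.8% of those tested; 230 rose and 401 fell by at least 1.5-fold. Of the other largest rises, DUSP5 reached 1.48 on the log2 scale, EIF4EBP2 1.36, C3orf52 1.36, SLC2A1 1.33, YOD1 1.31, H2BC5 1.28, STX3 1.21, FBXO32 1.19 and FTH1P3, a ferritin heavy chain pseudogene, 1.13. Of the other largest falls, TRIM5 reached -1.62, AQP9 -1.54, PRKAR1A, a regulatory subunit of protein kinase A, -1.53, TCEAL9 -1.52, ABCF2 -1.45, DPY19L1 -1.43, LRRC58 -1.42, IFI44L -1.38 and VOPP1 -1.38. Standard errors of these ran from 0.05 to 0.11. For FKBP1A, 1 of its 3 other probes was again called in the opposite direction (0.30), and the other probe for IFI44L gave -0.23. The probe for FTH1P3 was not checked for binding to related ferritin transcripts. CA2 fell by 0.65 (SE 0.09, adjusted p = 8.18e-05), CDKN1A rose (0.44, adjusted p = 3.23e-05), and RELA (-0.26, 0.00956), STAT3 (-0.33, 0.00663) and CCND1 (-0.20, 0.0123) fell; the CCND1 call did not hold with median scaling (0.427) or without control siRNA with TMZ replicate 2 (0.0509). NFKB1 (0.11, 0.199), NFKB2 (-0.02, 0.85), RELB (0.01, 0.952), MDM2 (-0.10, 0.522) and MSH6 (0.09, 0.364) did not pass.

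Both lists of the cell cycle were lower under TMZ as well. Of 32 genes of G1/S and DNA replication 21 fell and 1 rose (23 and 1 adjusted over the list alone; adjusted p = 1.31e-06, and adjusted p = 0.00587 with an estimated correlation), and of 35 genes of G2/M and mitosis 20 fell and 2 rose (22 and 3 adjusted over the list alone; adjusted p = 1.54e-05, and adjusted p = 0.0393 with an estimated correlation). KIF20A fell by 1.24 (SE 0.07), MKI67 by 1.14 (SE 0.08), BIRC5 by 1.09 (SE 0.06) and MCM6 by 0.63 (SE 0.06). Of 32 interferon response genes 15 fell and 0 rose (15 and 1 adjusted over the list alone), with ISG15 at -0.68; the adjusted p was 0.00537, and adjusted p = 0.211 with an estimated correlation. Of 26 hypoxia response genes 10 rose and 0 fell (10 and 0 adjusted over the list alone), with P4HA1 at 0.72, NDRG1 at 0.78 and DDIT4 at 0.68; the adjusted p was 0.0082, and adjusted p = 0.211 with an estimated correlation. No other list passed. NF-kB targets counted 3 rises and 11 falls of 27 (adjusted p = 0.156), with PLAU at -1.19 and IL1B at -1.23, p53 targets 13 and 5 of 36 (0.104) and ribosomal proteins 6 and 1 of 31 (0.0569).

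The effects of BCL3 siRNA under DMSO and under TMZ, which share no arrays, were alike across genes. The log2 fold changes correlated with r = 0.887 (Spearman's rho 0.838, covariance 0.0836) over 10686 genes, which are not independent replicates, and had the same sign in 82.2% of genes. In both conditions 1528 genes rose and 1651 fell, against 411.3 and 433.4 for independent lists of those sizes, and 2 genes were called in opposite directions. Both calls of a gene use the same estimate of its spread, so independent lists are only a rough reference.

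**Figure D2:**
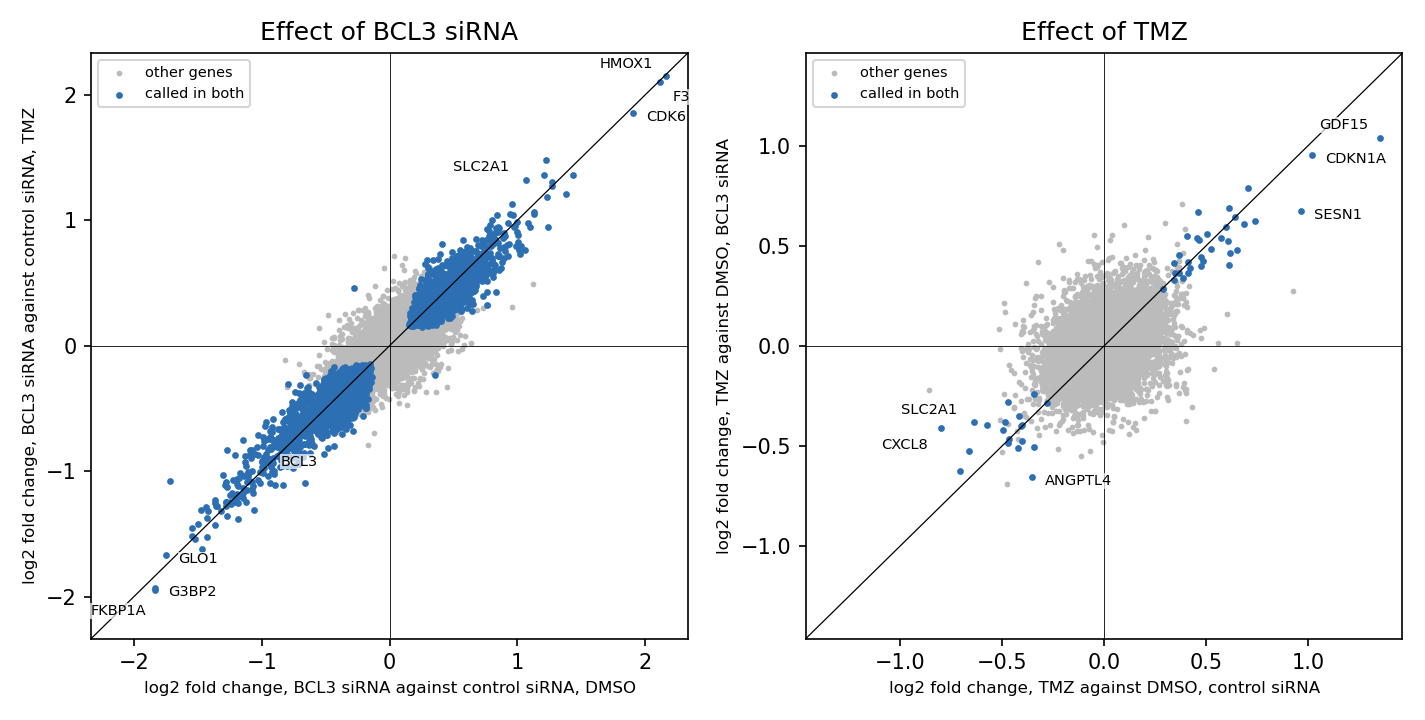
Log2 fold changes of 10686 genes. Left, BCL3 siRNA against control siRNA under DMSO (x axis) and under TMZ (y axis); right, TMZ against DMSO with control siRNA (x axis) and with BCL3 siRNA (y axis). Blue points are genes called in both comparisons of a panel, grey points the others, and the diagonal marks equal change; scales differ between panels. Across genes r was 0.887 on the left and 0.397 on the right.

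The third comparison asked what TMZ changed in cells with control siRNA. GDF15, a secreted stress cytokine and p53 target, rose 2.56-fold (log2 fold change 1.35, SE 0.06, n = 3 per group, adjusted p = 2.6e-07). CDKN1A rose 2.03-fold (SE 0.05 on the log2 scale, adjusted p = 3.66e-07) and SESN1 1.95-fold (SE 0.07, adjusted p = 1.06e-05), also known p53 targets. Among the falls, CSF3 (-0.86, SE 0.13), the chemokine CXCL8 (-0.80, SE 0.08) and SLC2A1 (-0.64, SE 0.06) were lower. Over all genes 50 rose and 42 fell, 0.9% of those tested, of which 13 rose and 5 fell by at least 1.5-fold. The other largest rises were those of the mitochondrial AARS2 (0.74), TP53INP1 (0.71), the damage recognition gene DDB2 (0.69), GCNT3 (0.65), SUGCT (0.64), the death receptor FAS (0.62, detected on 1 of the 3 DMSO arrays), the retinoic acid hydroxylase CYP26B1 (0.61), STOM (0.61) and TNFRSF14 (0.61). The other largest falls were those of NIM1K (-0.71), ZNF395 (-0.66), the NF-kB regulator TNIP1 (-0.57), IL1B (-0.51), MAFF (-0.51), ANKRD37 (-0.50), ARID3A (-0.48), F3 (-0.47) and BNIP3 (-0.47). Of genes fixed in advance, CA2 (0.30, adjusted p = 0.126), MDM2 (0.36, 0.18), CCND1 (-0.14, 0.244), RELA (-0.22, 0.14), RELB (-0.20, 0.257), NFKB2 (-0.17, 0.383), NFKB1 (0.06, 0.72), STAT3 (-0.02, 0.941) and MSH6 (-0.07, 0.685) did not pass.

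The p53 target list was the clearest group, with 12 of 36 members risen and 0 fallen, and 25 risen and 0 fallen when adjusted over the list alone. Besides those named, TRIM22 rose (0.57, SE 0.06), and 34 of 36 fold changes were above 0. The adjusted p was 7.89e-25, and adjusted p = 5.44e-05 with an estimated correlation. Of 26 hypoxia response genes 10 fell and 0 rose (13 and 0 adjusted over the list alone), among them SLC2A1, ANKRD37, BNIP3 and PFKFB3 (-0.41, SE 0.06); the adjusted p was 3.37e-17, and adjusted p = 0.00436 with an estimated correlation. G2/M and mitosis genes were higher, 2 risen and 0 fallen of 35 and 14 risen when adjusted over the list alone, with a median of 0.141 (adjusted p = 6.92e-10, and adjusted p = 0.00436 with an estimated correlation). NF-kB targets were lower, 3 fallen and 0 risen of 27 (7 and 1 adjusted over the list alone; adjusted p = 0.000373, and adjusted p = 0.0304 with an estimated correlation).

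The other lists that passed with camera's preset correlation did not pass with an estimated one. Interferon response genes were higher, with 1 of 32 risen and 0 fallen (3 and 0 adjusted over the list alone; adjusted p = 0.000708, and adjusted p = 0.15 with an estimated correlation). Extracellular matrix and adhesion genes were lower, with 0 of 32 called and 4 fallen when adjusted over the list alone (adjusted p = 0.00147, and adjusted p = 0.135 with an estimated correlation). STAT3 targets were lower, with 2 of 24 fallen, among them MYC (-0.41, SE 0.06), and 4 fallen and 1 risen when adjusted over the list alone (adjusted p = 0.0142, and adjusted p = 0.0979 with an estimated correlation); without control siRNA with DMSO replicate 1 the preset test gave 0.138. Ribosomal proteins (adjusted p = 0.792), G1/S and DNA replication (0.325), mesenchymal markers (0.157) and the leukocyte (0.991) and neuron and oligodendrocyte (0.342) markers did not pass.

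The number of genes called for TMZ depended on the settings. It was 416 without background correction, 370 with a mean-variance trend and robust moderation, 334 with normexp by maximum likelihood and an offset of 50, 290 with neqc and an offset of 50, and 243 with array weights. It was 148 over genes detected on all 12 arrays and 56 with only the 6 arrays compared in the fit. Without 1 array it fell to 36 (control siRNA with TMZ replicate 1), 44 (its replicate 2), 38 (control siRNA with DMSO replicate 1) or 47 (its replicate 2). The call of TP53INP1 did not hold without control siRNA with DMSO replicate 1 (adjusted p = 0.0588) or control siRNA with TMZ replicate 2 (0.0529), and that of IL1B without DMSO replicate 1 (0.0661) or TMZ replicate 1 (0.0724) of the same siRNA. That of MAFF did not hold without DMSO replicate 1 (0.0777) or 2 (0.0849) or TMZ replicate 1 (0.0983) or 3 (0.0739). MYC missed the threshold when probes were averaged (0.068), and CA2 passed it with 5 alternatives, with adjusted p from 0.0144 with averaged probes to 0.0432 with an offset of 50.

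The fourth comparison asked what TMZ changed in cells with BCL3 siRNA. GDF15 rose 2.06-fold (log2 fold change 1.04, SE 0.06, n = 3 per group, adjusted p = 3.45e-06) and CDKN1A 1.94-fold (SE 0.05 on the log2 scale, adjusted p = 1.72e-06). TP53INP1 (0.79, SE 0.11), TP53I3 (0.71, SE 0.10), STOM (0.69), SESN1 (0.67), the diacylglycerol kinase DGKA (0.67), SUGCT (0.64), AARS2 (0.63), the ribonucleotide reductase subunit RRM2B (0.61), DDB2 (0.61) and MICOS10 (0.60) rose. SPRY1, an inhibitor of receptor tyrosine kinase signalling (-0.69, SE 0.11), ANGPTL4 (-0.65, SE 0.06), NIM1K (-0.63), ABTB2 (-0.53), ZNF395 (-0.52), NDRG1 (-0.51), the glycolytic regulator PFKFB4 (-0.51), F3 (-0.49), MYC (-0.47), APLN (-0.47), the long non-coding RNA CYTOR (-0.44) and PANX1 (-0.44) fell. Over all genes 64 rose and 49 fell, 1.1% of those tested, of which 14 rose and 3 fell by at least 1.5-fold. CA2 (0.16, adjusted p = 0.412), MDM2 (0.51, 0.0631), CCND1 (-0.16, 0.209), RELA (-0.15, 0.333), RELB (0.01, 0.972), NFKB1 (-0.15, 0.306), NFKB2 (-0.04, 0.875), STAT3 (-0.08, 0.675) and MSH6 (-0.13, 0.414) did not pass.

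The p53 target list again stood out, with 14 of 36 members risen and 0 fallen, 22 and 0 adjusted over the list alone (adjusted p = 1.86e-23, and adjusted p = 6.78e-05 with an estimated correlation). TRIM22 (0.54) was among them. Of 26 hypoxia response genes 11 fell and 0 rose, 16 and 0 adjusted over the list alone, and all 26 fold changes were below 0 (adjusted p = 5.05e-18, and adjusted p = 0.00422 with an estimated correlation). ANGPTL4, PFKFB4, ANKRD37 (-0.42) and SLC2A1 (-0.38) fell. Homologous recombination and Fanconi anaemia genes were higher, with 0 of 23 called and 4 risen when adjusted over the list alone (adjusted p = 0.00594, and adjusted p = 0.0454 with an estimated correlation). G2/M and mitosis genes (adjusted p = 0.0907), NF-kB targets (0.149), interferon response genes (0.18), and the leukocyte (0.829) and neuron and oligodendrocyte (0.18) markers did not pass.

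Here too the count moved with the settings, to 287 without background correction, 276 with trend and robust moderation, 239 with normexp by maximum likelihood and an offset of 50, 229 with neqc and an offset of 50, and 29 with only the 6 arrays compared. Without 1 array it fell to 54 (BCL3 siRNA with DMSO replicate 2), 56 (its replicate 1), 60 (BCL3 siRNA with TMZ replicate 1), 67 (its replicate 3) or 70 (control siRNA with TMZ replicate 2). Median scaling called 40 rises and 60 falls, 40% rises against 56.6%. With only the 6 arrays compared, the calls of TP53INP1 (adjusted p = 0.0659), TP53I3 (0.0784), DDB2 (0.0574), SPRY1 (0.069), NDRG1 (0.094) and SLC2A1 (0.0777) were lost, as were those of the genes named next. That of RRM2B did not hold without BCL3 siRNA with DMSO replicate 2 (0.102) or 3 (0.0964) or with TMZ replicate 1 (0.0533) or 2 (0.0777), and that of APLN without DMSO replicate 1 (0.099) or 3 (0.0716) or TMZ replicate 1 (0.0819) or 3 (0.0947) of the same siRNA. That of NIM1K did not hold without its DMSO replicate 1 (0.0645) or 2 (0.0689), and that of PANX1 without DMSO replicate 3 (0.0528) or TMZ replicate 1 (0.055). The calls of MICOS10 and CYTOR each missed the threshold without any 1 of 10 arrays, with adjusted p up to 0.144 and 0.138 without BCL3 siRNA with TMZ replicate 1. MDM2 passed with 3 alternatives, with adjusted p from 0.0286 to 0.045, and without control siRNA with DMSO replicate 1 (0.0404). CYTOR also lost its call with averaged probes (-0.05, 0.864), since its other probe gave 0.34, with no filter (0.0625), with detection p under 0.05 (0.0521) and with the replicate block (0.0713). MICOS10 lost its call with median scaling (0.41, 0.0835), the authors' normalized intensities (0.0717), no filter (0.0652), detection p under 0.05 (0.0521) and the replicate block (0.0502), RRM2B with no filter (0.0576) and APLN with the replicate block (0.0502).

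The effects of TMZ with control siRNA and with BCL3 siRNA, which share no arrays, correlated with r = 0.397 (Spearman's rho 0.36, covariance 0.007) over all genes, which are not independent replicates, and with r = 0.827 over the 153 genes called in either. In both backgrounds 33 genes rose and 19 fell, against 0.3 and 0.2 for independent lists of those sizes, and 0 were called in opposite directions. The shared estimate of the spread makes independent lists a rough reference here too.

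The fifth comparison, the interaction, asked whether the response to TMZ differed between cells with BCL3 siRNA and cells with control siRNA. No gene passed with limma: 0 of 10686, with 718 genes at an unadjusted p under 0.05 and a lowest adjusted p of 0.0775. The genes with the lowest p were ADI1 (difference of log2 fold changes 0.68, SE 0.09, adjusted p = 0.0775), PTGES3 (0.58, SE 0.09, 0.145), ZNF585A (0.70, 0.347), TMPRSS12 (0.74, 0.433) and SSX3 (-0.58, 0.433), none past the threshold; ZNF585A and TMPRSS12 were not detected on any array of BCL3 siRNA with DMSO. With normexp by maximum likelihood and an offset of 50, without background correction, with neqc and an offset of 50 or with trend and robust moderation 1 gene passed. It was PTGES3, with adjusted p from 0.0104 to 0.0197. PTGES3 also passed without control siRNA with DMSO replicate 3 (0.049). Among the p53 targets, GDF15 gave -0.31 (SE 0.09, adjusted p = 0.579), SESN1 -0.29 (SE 0.10, 0.656) and CDKN1A -0.07 (SE 0.07, 0.899), and the list did not pass (0.799). CA2 gave -0.14 (SE 0.12, 0.87) and BCL3 0.23 (SE 0.10, 0.733). The other genes fixed in advance gave values from -0.21 for NFKB1 to 0.21 for RELB, with none past the threshold.

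One list passed for the interaction. The 35 genes of G2/M and mitosis had a lower TMZ response with BCL3 siRNA, with a median difference of -0.084, 30 of 35 below 0, and 0 called singly or when adjusted over the list alone (adjusted p = 0.00175). It did not pass with an estimated correlation (adjusted p = 0.229 with an estimated correlation) or with median scaling (0.154). KIF2C gave -0.32 (SE 0.09, adjusted p = 0.564) and CDCA8 -0.26 (SE 0.09, 0.65). The hypoxia list (0.991), the NF-kB targets (0.106) and homologous recombination and Fanconi anaemia (0.106) did not pass.

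**Figure D3:**
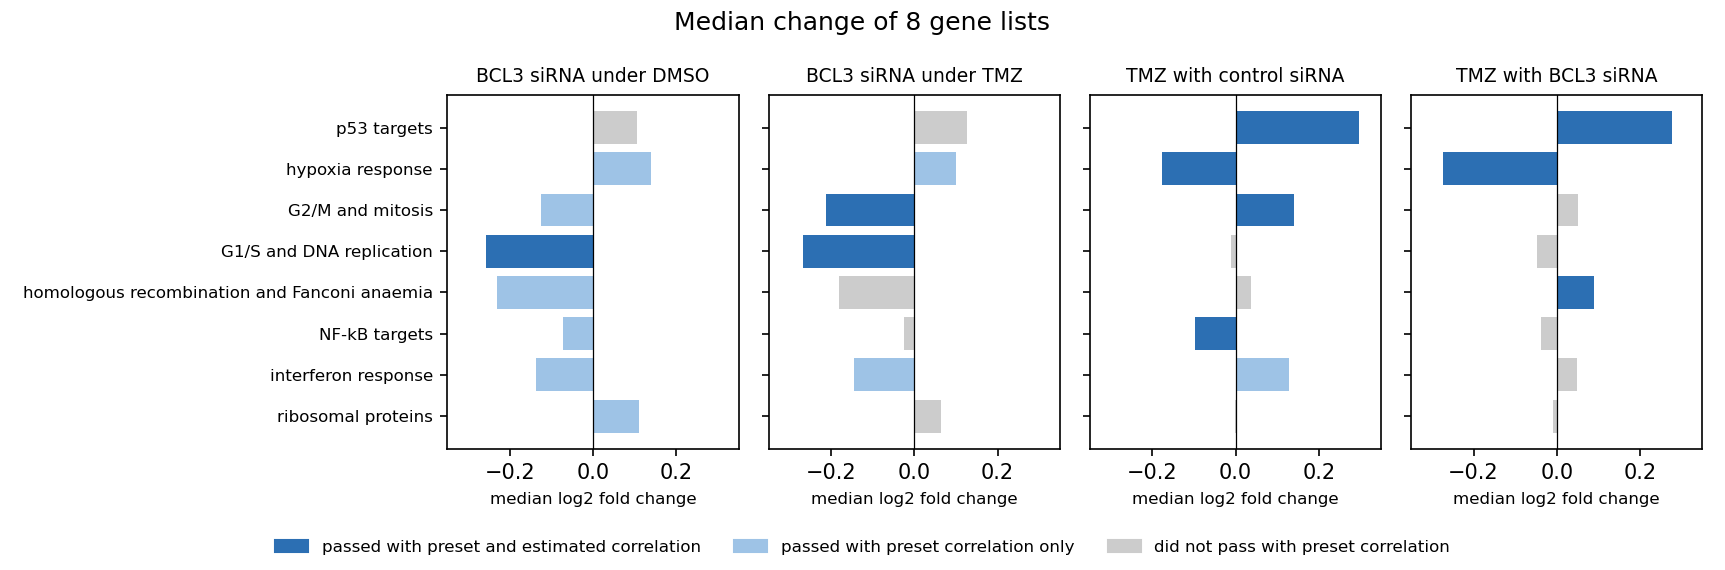
Median log2 fold change (x axis) of 8 gene lists (y axis) in the 4 pairwise comparisons of groups; bar colour shows whether the list passed camera at adjusted p under 0.05 with the preset and with an estimated correlation. The p53 list had medians of 0.296 and 0.276 with TMZ, and the hypoxia list had medians of 0.139 and 0.101 with BCL3 siRNA and of -0.176 and -0.273 with TMZ.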

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

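The tests of array brightness for the hypoxia list and of siRNA effects on other transcripts were chosen only after their results were seen, while the estimated correlation was itself chosen beforehand and only its use to weigh the G2/M result came after that result was seen; the others were chosen beforehand.

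The list of 35 genes of G2/M and mitosis had a lower TMZ response after BCL3 siRNA than after control siRNA with camera's preset correlation (adjusted p = 0.00175 for the interaction) but not with an estimated one (adjusted p = 0.229), and it drew attention because the difference itself was tested. The median difference was -0.084, with 30 of 35 genes lower and 0 called singly. The estimated correlation of the list was 0.025, against the preset 0.01. The estimated version also weakened some lists whose estimate lay below the preset. For G1/S and DNA replication with BCL3 siRNA under DMSO (-0.021) the unadjusted camera p went from 1.1e-07 to 0.000296. The loss of the G2/M result therefore does not show that correlated genes gave it, and that explanation stays open. Over the alternatives the adjusted p ran from 4.01e-05 to 0.229, with 0.154 under median scaling. A single array was argued against as the source of the preset result, since its adjusted p stayed at or under 0.0309 with each of the 12 arrays left out. A lower response of mitotic genes after BCL3 siRNA, which the design allows, may also be true and stays untested beyond these arrays.

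Detected probes without a gene symbol were left out of the gene tests, yet many changed when fitted by themselves with the same group-means model. Of 3835 such probes, 914 were called for BCL3 siRNA under DMSO (525 up and 389 down), 965 for BCL3 siRNA under TMZ (600 up and 365 down), 6 for TMZ with control siRNA and 4 for TMZ with BCL3 siRNA. For BCL3 siRNA the shares called were 23.8% under DMSO and 25.2% under TMZ, against 40.8% and 38.8% of named genes. These shares are not of the same kind. Named genes were counted by their brightest probe only and adjusted as a separate set, while all detected unnamed probes were counted. The called probes were signals in measured data that the comparisons of genes did not use. What these probes bind was not analysed here.

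BCL3 siRNA changed 40.8% of the genes under DMSO and 38.8% under TMZ, and 88 genes fell more than BCL3 in both. The BCL3 probe was dim, with raw intensities from 130.8 to 172 on arrays of BCL3 siRNA. Its fall is understated on the offset scale, so the 88 may be too many. The choice of quantile normalization was argued against as the cause of the number of changed genes, since the lower of the counts with median scaling and cyclic loess was 100% of the count under DMSO. Of the 4813 genes called with median scaling, 3875 were also called in the main run. Every alternative aligned the arrays in some way, so the count without normalization between arrays is not known. Of the genes changed by at least 1 log2 unit in both treatments, 67 fell and 13 rose, so that 83.8% fell. Action of the siRNA on transcripts other than BCL3 may give such a skew, and it cannot be told apart from loss of BCL3, because only 1 BCL3 siRNA condition was measured.

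The hypoxia list was lower under TMZ with both siRNAs, with medians of -0.176 and -0.273. With the log2 mean raw intensity of each array as a covariate the medians were -0.196 and -0.30, and the higher adjusted p was 1.87e-15 (0.0103 and 0.0125 with an estimated correlation), although the genes called fell from 92 to 28 and from 113 to 78. This argues against array brightness as the whole cause. A response of the cells to TMZ is a candidate explanation, and differences in culture density or medium between dishes are another, which the labels do not let be tested.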

How the results depend on the processing

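No test in this part was chosen after its result was seen, except where said. BCL3 kept its fall and its call in every alternative run, from -1.04 to -0.93 under DMSO and from -0.78 to -0.73 under TMZ with 1 array left out, and was smallest with no background correction (-0.60 and -0.47). The cause was not tested for any change given below except where the alternative itself tests fewer genes, uses fewer arrays or asks for a larger change.

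Among genes called, normexp by maximum likelihood with an offset of 50 gave 334 for TMZ with control siRNA, 239 for TMZ with BCL3 siRNA and 1 for the interaction. In the same order, no background correction gave 416, 287 and 1, and neqc with an offset of 50 gave 290, 229 and 1. Trend and robust moderation gave 370, 276 and 1. Array weights gave 243 and detection on all 12 arrays 148 for TMZ with control siRNA. Only the 6 arrays compared gave 56 and 29 for TMZ with each siRNA, with fewer arrays to estimate the spread. A change of at least 1.5-fold left 654 and 631 for BCL3 siRNA under DMSO and TMZ, and 18 and 17 for TMZ with control and BCL3 siRNA. With 1 array left out the counts ran from 3610 to 4376 and from 3384 to 4181 for BCL3 siRNA under DMSO and TMZ, from 36 to 100 and from 54 to 102 for TMZ with control and BCL3 siRNA, and from 0 to 1 for the interaction.

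The replicate block, which treats equal replicate numbers as paired, called 4236, 4045, 81, 82 and 0 genes in the 5 comparisons. Residuals of equal numbers correlated from -0.15 to 0.19. A slide or chip block was not run since the files name none.

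Among the 23 lists, 7, 4, 7, 3 and 1 were called in the 5 comparisons. For the interaction 2 were called with normexp, no background correction or an offset of 50, 3 with detection on all 12 arrays, and 0 with median scaling or an estimated correlation. For TMZ with BCL3 siRNA 5 were called with no background correction or median scaling, 6 with no filter and 9 with fry. An estimated correlation called 1 and 2 for BCL3 siRNA under DMSO and TMZ and 4 for TMZ with control siRNA; fry called 18 and 14 for BCL3 siRNA. With 1 array left out the lists called ran from 5 to 8, 4 to 5, 6 to 7, 3 to 5 and 1 to 2.

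The correlation across genes between the effects of BCL3 siRNA was 0.926 over genes called in either, 0.917 with normexp, 0.923 with no background correction, 0.869 with median scaling, 0.915 with an offset of 50, 0.831 with no filter, 0.912 with detection on all 12 arrays and 0.866 with detection p under 0.05. That between the effects of TMZ was 0.827, 0.476, 0.496, 0.314, 0.471, 0.289, 0.466 and 0.35 in the same order. With 1 array left out they ran from 0.869 to 0.884 and from 0.325 to 0.418.

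Among named genes, all reversals were of genes not called. With median scaling RELB gave -0.01 for BCL3 siRNA under TMZ and -0.06 for TMZ with BCL3 siRNA, and MDM2 gave -0.08 for the interaction. Cyclic loess gave RELB 0.00 under TMZ, and array weights gave STAT3 0.01 for TMZ with control siRNA and RELB 0.00 for TMZ with BCL3 siRNA. With 1 array left out, STAT3 ran from -0.09 to 0.03 for TMZ with control siRNA and from -0.13 to 0.00 for the interaction, RELB from -0.03 to 0.05 for BCL3 siRNA under TMZ and from -0.01 to 0.04 for TMZ with BCL3 siRNA, NFKB2 from -0.10 to 0.06 for BCL3 siRNA under TMZ, and CCND1 from -0.05 to 0.02 for the interaction. Of the other values of named genes, 2481 with an array left out and 2885 with other alternatives kept direction and side of the threshold, 46 and 27 lost it, and 4 and 17 gained it. The offset and the low signal of dim probes over background limit what can be detected.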

Other observations

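The averaged effects and the splits of the interaction were chosen only after the data were seen. Averaged over both siRNAs, TMZ raised 290 genes and lowered 227, and 376 of these 517 were called in neither comparison alone. BAX, the apoptosis effector of the p53 pathway, rose by 0.60 on the log2 scale (SE 0.15, limma adjusted p = 0.0406) and MDM2, which encodes the ubiquitin ligase of p53, by 0.43 (SE 0.08, 0.0127). CSMD3 rose (0.42, 0.0088), and TMEM45A (-0.43, 0.00536), the stress gene GADD45B (-0.43, 0.00355) and the cytokine signalling inhibitor SOCS3 (-0.37, 0.0049) fell. These genes were named after their values were seen.

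In the averaged TMZ effect 21 of 36 p53 targets rose and 0 fell (camera, adjusted p = 6.45e-27, and 3.98e-05 with an estimated correlation). Of 26 hypoxia response genes 14 fell and 0 rose (8.6e-21, and 0.00257). Of 35 genes of G2/M and mitosis 8 rose and 0 fell (1.24e-06, and 0.0164). NF-kB targets, with 1 risen and 5 fallen of 27, passed with the preset correlation (0.00396) but not with an estimated one (0.0824). The same held for interferon response (0.00396 and 0.161), homologous recombination and Fanconi anaemia (0.0427 and 0.0941) and apoptosis regulators (0.0439 and 0.0941), which were higher. It also held for extracellular matrix and adhesion (0.00396 and 0.134) and STAT3 targets (0.0161 and 0.0941), which were lower. Averaged over both treatments, BCL3 siRNA raised 2908 genes and lowered 2855, and 717 of these were called in neither comparison alone.

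Other groupings of the arrays were tried for each count. For each comparison of 3 arrays with 3 there are 10 splits, so the share that gives as many calls cannot go under 0.1; the real split was the 1 with as many, with 4362, 4141, 92 and 113 genes in the order of the report and 0, 0, 0 and 1 as the highest of the others. For the interaction the real count was 0, so that all 100 of 100 drawn splits had to give as many and the splits decide nothing; the highest other gave 2. For the averaged effects 1 of 100 drawn splits, the real one, gave as many. It called 517 genes for TMZ against 2 at most in others, and 5763 for BCL3 siRNA against 1. This argues against chance differences between single arrays. If the 3 arrays of a group came from 1 culture, which the labels leave open, differences between cultures would give the same outcome. The splits cannot tell these from effects of TMZ or siRNA.

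For some lists that did not pass, the median, the mean and the direction of the test differed in sign. With BCL3 siRNA these were mismatch repair, the NF-kB and I-kappa-B family and heat shock and oxidative stress in both treatments, and apoptosis regulators and the unfolded protein response under TMZ. With TMZ they were proneural markers, heat shock and oxidative stress, ribosomal proteins and leukocyte markers after control siRNA, and mismatch repair, stemness and leukocyte markers after BCL3 siRNA. For the interaction they were G1/S, STAT3 targets, mesenchymal markers, apoptosis regulators, cholesterol biosynthesis, oxidative phosphorylation and leukocyte markers.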
